A study of Mus musculus with 24 samples.

How the data were processed

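RNA was profiled on NimbleGen 12x135K mouse arrays, read in one colour with Cy3, in 24 samples. The labels give 4 kidney groups of 4 mice each, wild type or Chga knockout (chromogranin A gene disrupted, on a mixed C57BL/6 and 129 background), after sham surgery or 5/6 nephrectomy. Kidney was collected 10 weeks later. There were also 2 groups of 4 samples of CRL-1927 mouse mesangial cells, with or without recombinant CHGA protein. Whether the cell samples came from separate cultures is not given in the sources used here, so p-values for the cells measure the spread between samples of unknown independence. Those for kidney measure the spread between 4 mice per group.

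Per the file headers, the deposited per-array files hold 1 intensity per transcript feature on the linear scale, made by the authors with RMA (robust multi-array average, version not given in the sources used here). They summarise 3 probes for 44155 of 44170 features, 2 probes for 9 and 1 probe for 6. A further entry in each file summarises 5000 random control probes and was used as the background level of the array. Positions are the MM9 positions printed in the files. Gene symbols were updated through the gene identifiers in the files where the reference held them (39057 features matched, 5650 symbols changed), which left 41886 features with a symbol, for 24171 genes, and 2284 without. Several features were held by 10215 genes. With 3 probes per feature, paralogs of near-identical sequence (Ren1 and Ren2, Amy2a5 and Amy2b, Try4 and Prss2, Lyz1 and Lyz2, Hbb-b1 and Hbb-b2, and Klk1b22 with the other kallikreins) were read as gene families whose members were not resolved with certainty.

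The authors also deposited a value table in log2 units. From its values, each feature was centred on its median over the 24 columns, so that a positive value lies above that median. Its column medians were -0.011, -0.01, -0.02 and -0.027 for wild-type sham, -0.027, -0.011, -0.017 and -0.026 for knockout sham, -0.007, -0.01, -0.004 and -0.014 for wild-type nephrectomy, -0.013, -0.023, -0.022 and -0.015 for knockout nephrectomy, 0.046, 0.045, 0.037 and 0.038 for control cells and 0.047, 0.049, 0.043 and 0.044 for CHGA-treated cells. It was not a plain log2 of the per-array files: the median within-feature SD of the difference was 0.459, and 0.127 among the brightest features. In 8 of the 8 columns of knockout sham and wild-type nephrectomy, the table matched the same-numbered array of the other group. The 16 other columns matched their own array. The per-array files were therefore analysed with the sample labels of the series, and the values of the deposited table served as an alternative, both with columns as labelled and with columns matched to arrays.

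Intensities were transformed to log2 and compared with limma 3.58.1 (lmFit and eBayes, two-sided moderated test) in R 4.3.3 with version 1.17.8 of the data.table package. Data were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. All 16 kidney arrays entered a single fit with 12 residual degrees of freedom, and the 8 cell arrays a fit with 6. No feature was left out. P-values were adjusted by Benjamini-Hochberg over the 44170 features within each comparison, with a threshold of 0.05. A ± after a log2 change is the moderated standard error of the fit, and a ± after a level is the SD over the arrays of a group. The comparisons were nephrectomy against sham within each genotype, knockout against wild type within each surgery, the difference between the nephrectomy effects of the genotypes, and CHGA against control cells. The mean nephrectomy effect over both genotypes and the mean genotype effect over both surgeries were added after the data were seen.

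The 33 gene lists were tested with camera, on 1 feature per gene (the brightest), with a preset inter-gene correlation of 0.01 and, as an alternative, a correlation estimated per list. P-values were adjusted over the 33 lists. They covered fibrosis and extracellular matrix, tubule injury, macrophages, lymphocytes, neutrophils, inflammatory cytokines and NF-kB targets, interferon response and complement. Others covered nephron segments (proximal, distal, podocyte), mesangial and smooth muscle, endothelium, renin-angiotensin-aldosterone, nitric oxide and endothelin, and granins and catecholamines. Further lists covered fatty acid oxidation, oxidative phosphorylation, hypoxia, cell cycle, unfolded protein response, oxidative stress, cholesterol synthesis, immediate early genes and heat shock. The last held adrenal, adipocyte, erythroid and skeletal muscle markers, genes higher in kidneys of male or female mice, sex chromosome genes and housekeeping genes. Another 4 lists (pancreatic acinar, pancreatic islet, liver, circadian clock) were written after the data were seen and adjusted among themselves.

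Named genes followed a rule, applied to features with a gene symbol. It took Chga, and the 8 largest rises and 8 largest falls past the threshold whose groups did not overlap. From each called list it took up to 4 members past the threshold or, where none passed, the 2 with the largest change, as values only. From a list not called it took up to 2 members in the same way. Where fewer than 3 features passed, it took the 4 with the smallest p in each direction, as values only. Genes chosen outside it are marked as such. A further list member that the rule took is not reported here. The lists, the comparisons other than the 2 mean effects, the rule and the first set of alternatives below were chosen before the data were examined. Where every array of the lower group was at or below its random-probe level, a fold is given as "at least" and is taken from that level. Where only some arrays were above it, the change is also given with the values below it raised to it, array by array, as chosen after the data were seen.

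This first set held quantile normalization within the fit, median centring of each array, the value table as labelled, only features above the median level, and features of a gene averaged. It also held eBayes with trend and robust settings, array weights, the replicate number as a block, a fold of at least 1.5, only the 2 groups compared, only the arrays of slide 2, camera with estimated correlation, and each array left out in turn. Added after the data were seen were the table with matched columns, the knockout sham and wild-type nephrectomy arrays exchanged, the random-probe level as a covariate, wild-type sham arrays 3 and 4 left out, and acinar features left out. The replicate numbers did not pair the samples: over 24 pairs of kidney arrays with the same number, residual correlations ranged from -0.203 to 0.12 with 1 above 0.1.

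Array data carry no read depth, so the number of arrays limits the precision. The median standard error of a log2 change was 0.58 between 2 kidney groups, 0.41 for the 2 mean effects, 0.82 for the difference of effects and 0.38 in cells. Within groups, the median SD of the dimmest features was 1.33 in kidney and 1.29 in cells, and that of the brightest 0.43 and 0.21 (features split into 4 equal classes by level). The procedure was tested on simulated data with 50 changed features per size. With the kidney design, 2%, 36%, 42% and 84% of changes of 1, 2, 3 and 4 log2 units were recovered, and 2.38% of the calls were false. With the cell design, 12%, 48%, 64% and 68% were recovered, and 10.3% of the calls were false. Of 200 unshifted lists, 3% had p below 0.05 in the kidney design and 8% in the cell design, and lists shifted by 0.5 were found in 96% and 100%. The simulated errors were independent between features, with no slide or background structure. The simulation therefore cannot show how camera with the preset correlation does for lists of correlated genes.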

Results

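The series concerns chromogranin A, a prohormone stored in the secretory granules of neuroendocrine cells, and what it does in the failing kidney. Expression was measured on 24 arrays. There were 4 arrays each from wild-type sham, knockout sham, wild-type nephrectomy and knockout nephrectomy kidneys, and 4 each from control and CHGA-treated CRL-1927 mesangial cells. The arrays had a median feature intensity of 273.8 to 309.2. The random control probes, the background of each array, lay at 116 ± 29.9 (SD, n = 4) in wild-type sham, 113 ± 15.8 in knockout sham, 77.1 ± 3.90 in wild-type nephrectomy and 85.7 ± 8.12 in knockout nephrectomy. In the cells they lay at 96.4 ± 2.93 without and 97.1 ± 4.47 with CHGA. The share of features above this level was 76.8%, 77.4%, 84.5%, 82.9%, 79.8% and 79.7% in the same order.

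By the file names the wild-type sham arrays shared a slide with the cells, and the other 3 kidney groups shared a second slide. In both comparisons with wild-type sham the slide and the group therefore cannot be told apart. All kidney results rest on the sample labels of the per-array files. The deposited value table carries the knockout sham and wild-type nephrectomy columns exchanged against those files. With its columns as labelled, nephrectomy gives 1 feature in each genotype and 5 over both. Genotype then gives 106 in sham kidney, 41 after nephrectomy and 455 over both surgeries, and several directions turn. The exchange turns each nephrectomy comparison into a genotype comparison, so this trade of counts follows by construction.

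**Figure D1:**
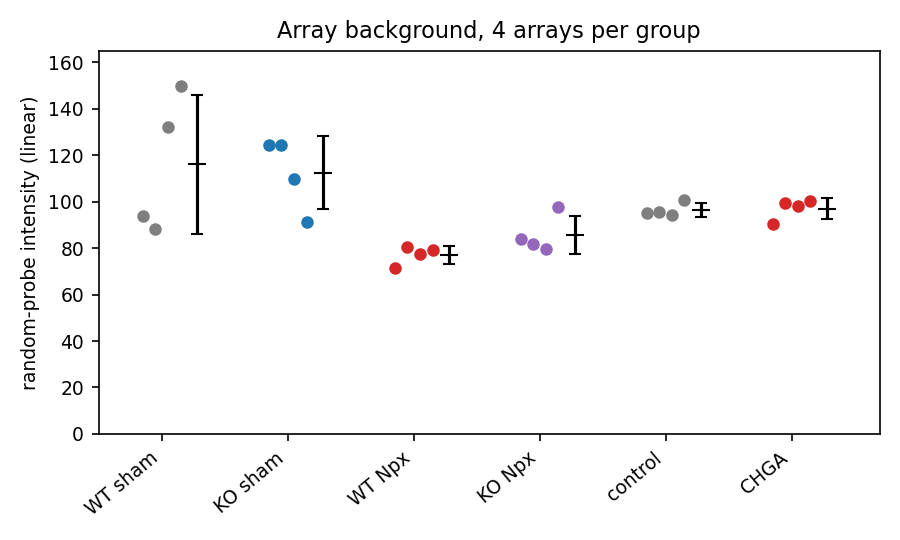
Intensity of the random control probes (linear scale, vertical axis from 0) in the 6 groups, where points are arrays and the black mark is the mean ± SD of 4 arrays. The mean of the 8 sham kidney arrays is higher than that of the 8 nephrectomized ones on the log2 scale (6.81 ± 0.28 against 6.34 ± 0.13), and the 2 sets overlap.

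In wild-type mice, the kidney left after 5/6 nephrectomy was compared with sham kidney to describe the failing kidney itself. Matrix transcripts were among those that rose. Lum, a collagen-binding proteoglycan (feature BC005550, MM9 chromosome 10, 97028456 to 97035336), rose 14.5-fold, from a log2 intensity of 6.94 ± 0.54 to 10.8 ± 0.18 (mean ± SD, n = 4 each). Col3a1, a fibrillar collagen (BC043089, chromosome 1, 45368507 to 45405865), rose 14-fold, from 7.91 ± 1.33 to 11.72 ± 0.65, and Col1a2, a chain of type I collagen, rose 4.53-fold. Renin transcripts fell. Ren1, the protease that starts angiotensin formation (BC061053, chromosome 1, 135247252 to 135256862), went from 12.36 ± 0.48 to 9.2 ± 0.34, 8.93-fold lower. Its paralog Ren2 was 7.95-fold lower on 1 feature and fell by 3.48 ± 0.41 log2 units on the other (± standard error of the fit, as for all log2 changes below).

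The largest rises belonged to digestive enzymes of the exocrine pancreas. Try4, a trypsinogen (BC061135, chromosome 6, 41252270 to 41255530), rose 86.9-fold, from 7.12 ± 1.76 to 13.57 ± 1.4. Amy2a5, pancreatic amylase (NM_009669, chromosome 3, 113052094 to 113061615), rose 76-fold, from 7.68 ± 0.95 to 13.93 ± 0.85. Pancreatic lipase (Pnlip) rose 76.9-fold, its cofactor colipase (Clps) at least 25.8-fold, amylase Amy2b 25.6-fold and trypsinogen Prss2 24.4-fold. Popdc3, a membrane protein of muscle, rose 25.2-fold, and Krt19, a keratin of ductal epithelium, rose 15.4-fold. The nonagouti gene (symbol a), which controls coat colour, was at least 1.43-fold lower. The other 4 rises lay outside the rule for named genes and were named after their values were seen. They were Eln (elastin, 9.83-fold), Ctsk (cathepsin K, a collagen-degrading protease, 11.7-fold), Celf2 (an RNA-binding protein, 5.12-fold) and Lsp1 (a leukocyte actin-binding protein, 3.40-fold). In wild-type sham, Popdc3 was above the random-probe level on 1 of 4 arrays, Krt19 on 2, and Lum, Col3a1, Try4, Amy2a5, Pnlip and Ctsk on 3. With the values below that level raised to it, the folds of these 8 genes were 12.4, 11.1, 12.9, 11.6, 61.7, 65.1, 47.4 and 11.1.

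Of 26 measured matrix genes 3 rose, 0 fell and 23 did not pass, while 24 rose adjusted over the list alone. The list's median change was 2.1 and its camera adjusted p was 3.99e-27. Of 21 tubule injury genes Krt19 rose and 20 did not pass, while 9 rose adjusted over the list alone, with a median of 1.34 and an adjusted p of 1.37e-11. These 2 lists also passed with an estimated correlation, each at an adjusted p of 0.0442, and the other 18 called lists did not. Macrophage markers had a median of 1.06, with 0 of 20 members past and 8 adjusted over the list alone (Ccr2 at 2.85 ± 0.72, Mpeg1 at 2.06 ± 0.79). Complement genes had a median of 1.23, with 0 of 14 past and 8 adjusted over the list alone (C3 at 3.1 ± 0.52, C3ar1 at 2.21 ± 0.42). Both lists had an adjusted p = 0.121 with an estimated correlation, against 1.35e-07 and 1.47e-07 with the preset one. Mesangial and smooth muscle markers had a median of 0.98, with 0 of 17 past and 8 adjusted over the list alone (Acta2 at 1.98 ± 0.37, Tagln at 1.72 ± 0.35). Their adjusted p was 9.77e-07, and adjusted p = 0.057 with an estimated correlation. Immediate early genes, transcription factors induced first by a stimulus, had a median of 0.65, with 0 of 20 past and 6 adjusted over the list alone (Egr2 at 2.27 ± 0.72, Fos at 2.11 ± 0.73). Their adjusted p was 0.000283, and adjusted p = 0.161 with an estimated correlation. Ccr2, Egr2 and Fos, each above the random-probe level on 2 of 4 wild-type sham arrays, were at 1.63, 1.77 and 1.93 with the values below it raised to it.

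The other lists called upward in wild type had 0 members past over all features. Lymphocyte markers had a median of 0.82, endothelial markers 0.87, nitric oxide and endothelin genes 0.82 and cell cycle genes 0.73. The adjusted p of these 4 with an estimated correlation was 0.141, 0.183, 0.177 and 0.13. Adjusted over the list alone, 3 of 19 lymphocyte markers and 1 of 23 nitric oxide and endothelin genes rose. NF-kB targets had a median of 0.51, cholesterol synthesis genes 0.56, distal nephron genes 0.5, podocyte markers 0.36 and genes of the unfolded protein response 0.45. The adjusted p of these 5 with an estimated correlation was 0.208, 0.205, 0.418, 0.284 and 0.161. Adjusted over the list alone, 1 of 26 NF-kB targets and 1 of 16 podocyte markers rose. Hypoxia genes had a median of 0.26 (1 of 19 fell adjusted over the list alone, adjusted p = 0.418 with an estimated correlation). Genes higher in female kidney had one of 1.18 (2 of 6 rose adjusted over the list alone, adjusted p = 0.25 with an estimated correlation). With the random-probe level as a covariate 4 of these medians turned negative, to -0.51 for distal nephron genes, -0.42 for podocyte markers, -0.04 for endothelial markers and -0.14 for hypoxia genes.

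The camera test called 3 lists downward in wild type, again with 0 members past. Genes higher in male kidney had a median of -0.65 (Slc7a13 at -1.57 ± 0.64, Cyp7b1 at -1.41 ± 0.63), with adjusted p = 0.316 with an estimated correlation. Erythroid markers had a median of -1.06 (3 of 9 fell adjusted over the list alone, Hbb-b2 at -3.11 ± 0.87, Hbb-b1 at -2.25 ± 0.69), with adjusted p = 0.183 with an estimated correlation. Oxidative phosphorylation genes had a median of -0.15, with adjusted p = 0.342 with an estimated correlation. Proximal tubule transport (median 0.05, adjusted p = 0.641) and interferon genes (-0.01, adjusted p = 0.997) were not called. In the renin-angiotensin-aldosterone list, also not called, Ren1 alone of 15 genes passed.

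In the limma fit 15 features were higher and 4 lower after nephrectomy in wild type, with adjusted p-values for the named genes of 0.00148 (Amy2a5) to 0.0462 (Lsp1). An unadjusted p under 0.05 was reached by 5377 features, against 2208 by chance, and in 6.70% of features the groups did not overlap, against 2.86% by chance. The acinar transcripts rose in the same comparison (median change of 27 acinar genes 3.82, a list written after the data were seen), and the random-probe level was lower after nephrectomy. Wild-type sham arrays 3 and 4 had a 75th percentile of intensity of 1189.4 and 1024.7, against 1373.4 and 1366.5 on arrays 1 and 2. Their random-probe intensity was 132.1 and 150, against 94 and 88.1. The count was 3 without both of them, a run chosen after the data were seen, and 6 without array 3 alone. It was 9 without wild-type nephrectomy array 1 and 10 without array 3 of that group. It was 1 with the random-probe level as a covariate, 0 with only the 2 compared groups fitted, 179 with trend and robust eBayes and 143 with only features above the median level.

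**Figure D2:**
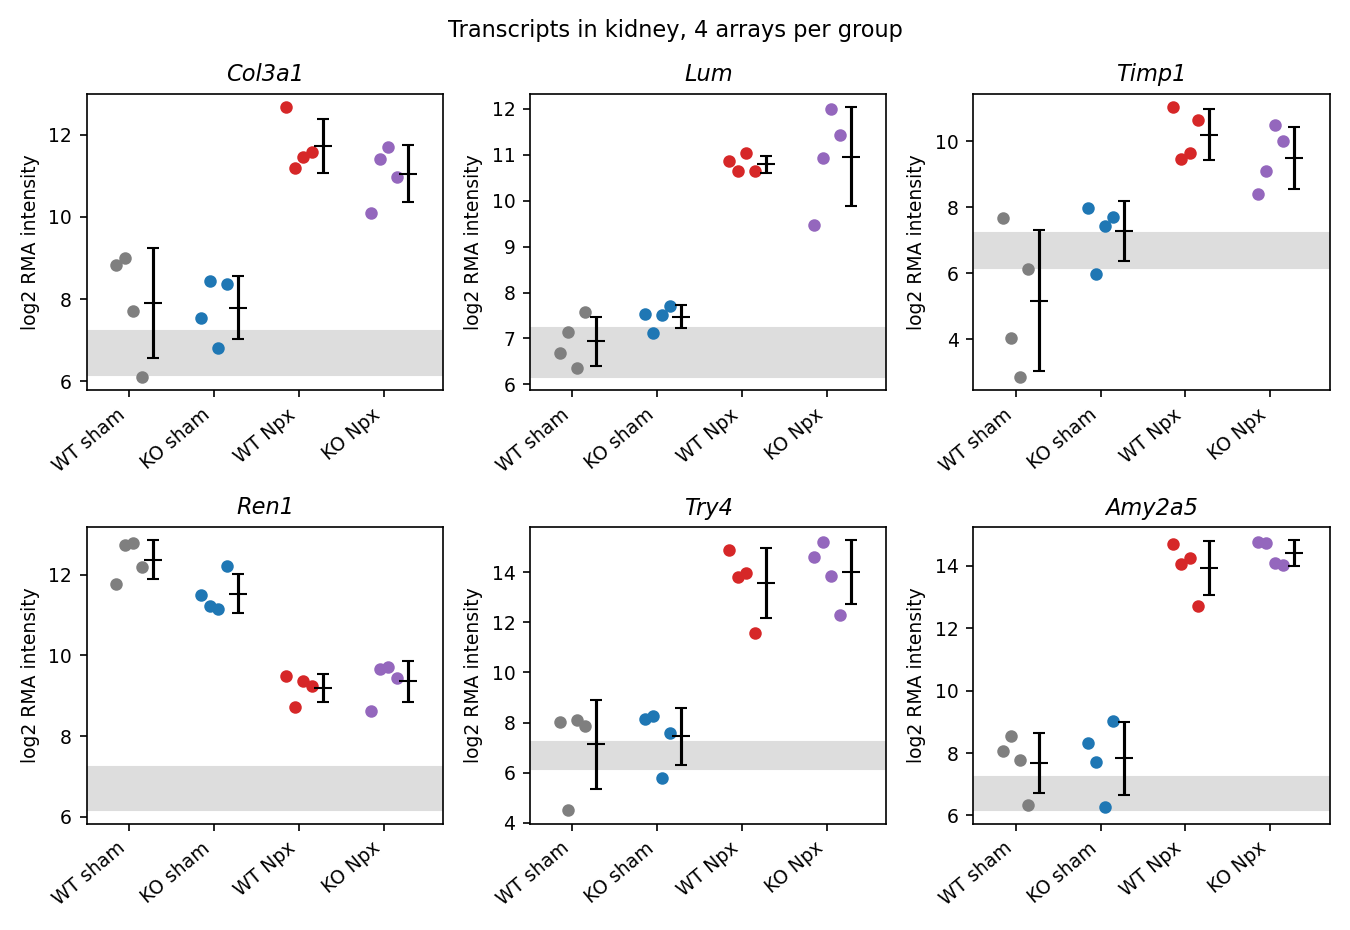
Log2 RMA intensity of Col3a1, Lum, Timp1, Ren1, Try4 and Amy2a5 in the 4 kidney groups, where points are arrays, the black mark is the mean ± SD of 4 arrays and the grey band is the range of the random-probe level over the arrays. In both genotypes the mean of the matrix and acinar genes is higher, and that of Ren1 lower, in the nephrectomy group.

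The same comparison in knockout mice asks how the kidney without chromogranin A responds to nephrectomy. Lum rose 11.3-fold, from 7.47 ± 0.25 to 10.97 ± 1.08 (n = 4 each), and Ren2 was 4.31-fold lower. Ren1 was at -2.16 ± 0.36, with an adjusted p of 0.0543 in limma. Pancreatic enzymes again had the largest rises. Amy2a5 rose 96.1-fold (7.83 ± 1.17 to 14.41 ± 0.4), Try4 93.7-fold (7.45 ± 1.14 to 14 ± 1.27), Prss2 73.8-fold, Pnlip 71.2-fold, Clps 56-fold and Amy2b 30.7-fold. Zg16, a zymogen granule protein, rose 57.6-fold, and Slc28a2, a nucleoside transporter, at least 2.92-fold. Plek (pleckstrin, a protein kinase C substrate of blood cells, 5.03-fold) and Gnl3l (a nucleolar GTP-binding protein, 4.86-fold) were the only other rises and were named after their values were seen. In knockout sham, Clps and Prss2 were above the random-probe level on 1 of 4 arrays, Zg16 and Gnl3l on 2, and Amy2a5, Try4 and Pnlip on 3. With the values below that level raised to it, the folds of these 7 genes were 37.5, 65.5, 32.8, 3.62, 87.9, 79 and 67.4.

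Of 26 matrix genes Lum rose and 25 did not pass, while 15 rose adjusted over the list alone. The median was 1.4, with an adjusted p of 6.44e-21, and adjusted p = 0.0581 with an estimated correlation. Tubule injury genes had a median of 0.69, with 0 of 21 past and 5 adjusted over the list alone (Cd44 at 2.87 ± 0.95, Krt20 at 2.08 ± 0.76, adjusted p = 0.0866 with an estimated correlation). Macrophage markers had a median of 0.61, with 0 of 20 past and 7 adjusted over the list alone (Mpeg1 at 3.36 ± 0.79, Cx3cr1 at 2.91 ± 0.7, adjusted p = 0.0919 with an estimated correlation). Complement genes had a median of 0.71, with 0 of 14 past and 2 adjusted over the list alone (C3 at 2.36 ± 0.52, adjusted p = 0.0919 with an estimated correlation). Cell cycle genes had a median of 0.89, with 0 of 25 past and 4 adjusted over the list alone (Mcm6 at 2.48 ± 0.8, Cenpf at 2.26 ± 0.62, adjusted p = 0.0581 with an estimated correlation). Endothelial markers had a median of 0.93, with 0 of 19 past and 1 adjusted over the list alone (Flt1 at 1.83 ± 0.48, Cdh5 at 1.49 ± 0.73, adjusted p = 0.0919 with an estimated correlation). Raising the values below the random-probe level to it put Cd44 at 1.54, Krt20 at 1.78, Mpeg1 at 2.88, Cx3cr1 at 2.41, Mcm6 at 1.92 and Cenpf at 1.3.

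A further 10 lists were called upward in the knockout with 0 members past. Mesangial and smooth muscle markers had a median of 0.74, NF-kB targets 0.55, podocyte markers 0.78, nitric oxide and endothelin genes 0.56 and interferon genes 0.73. The adjusted p of these 5 with an estimated correlation was 0.0866, 0.0919, 0.113, 0.113 and 0.312. Distal nephron genes had a median of 0.42, proximal tubule transport 0.38, fatty acid oxidation 0.31, cholesterol synthesis 0.27 and immediate early genes 0.27. The adjusted p of these 5 with an estimated correlation was 0.317, 0.447, 0.447, 0.384 and 0.317. Adjusted over the list alone, 1 NF-kB target, 3 distal nephron genes and 2 immediate early genes rose. With the random-probe level as a covariate the median turned to -0.13 for distal nephron genes, -0.09 for fatty acid oxidation and -0.01 for cholesterol synthesis, and was 0 for proximal tubule transport. Over the alternatives the lowest median was 0.08 for endothelial markers, 0.2 for podocyte markers and 0.1 for nitric oxide and endothelin genes.

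In limma 11 features were higher and 1 lower in the knockout. An unadjusted p under 0.05 was reached by 3749 features, and 5.35% did not overlap against 2.86% by chance. All 19 features called in wild type had the same sign here and 8 were past the threshold in both. Apart from Lum and Ren2, these 8 were the pancreatic genes Amy2a5, Amy2b, Try4, Prss2, Pnlip and Clps. Both groups lay on slide 2, and the acinar list had a median change of 4.47. Leaving out knockout sham arrays 1, 2, 3 and 4 in turn gave 6, 6, 3 and 23 features, leaving out knockout nephrectomy arrays 1, 2 and 3 gave 7, 3 and 6, and without the acinar features the count was 0. It was 2 with the random-probe level as a covariate, 3 with only the 2 compared groups fitted, 5 with the replicate block, 29 with array weights, 51 with trend and robust eBayes and 39 with only features above the median level.

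**Figure D3:**
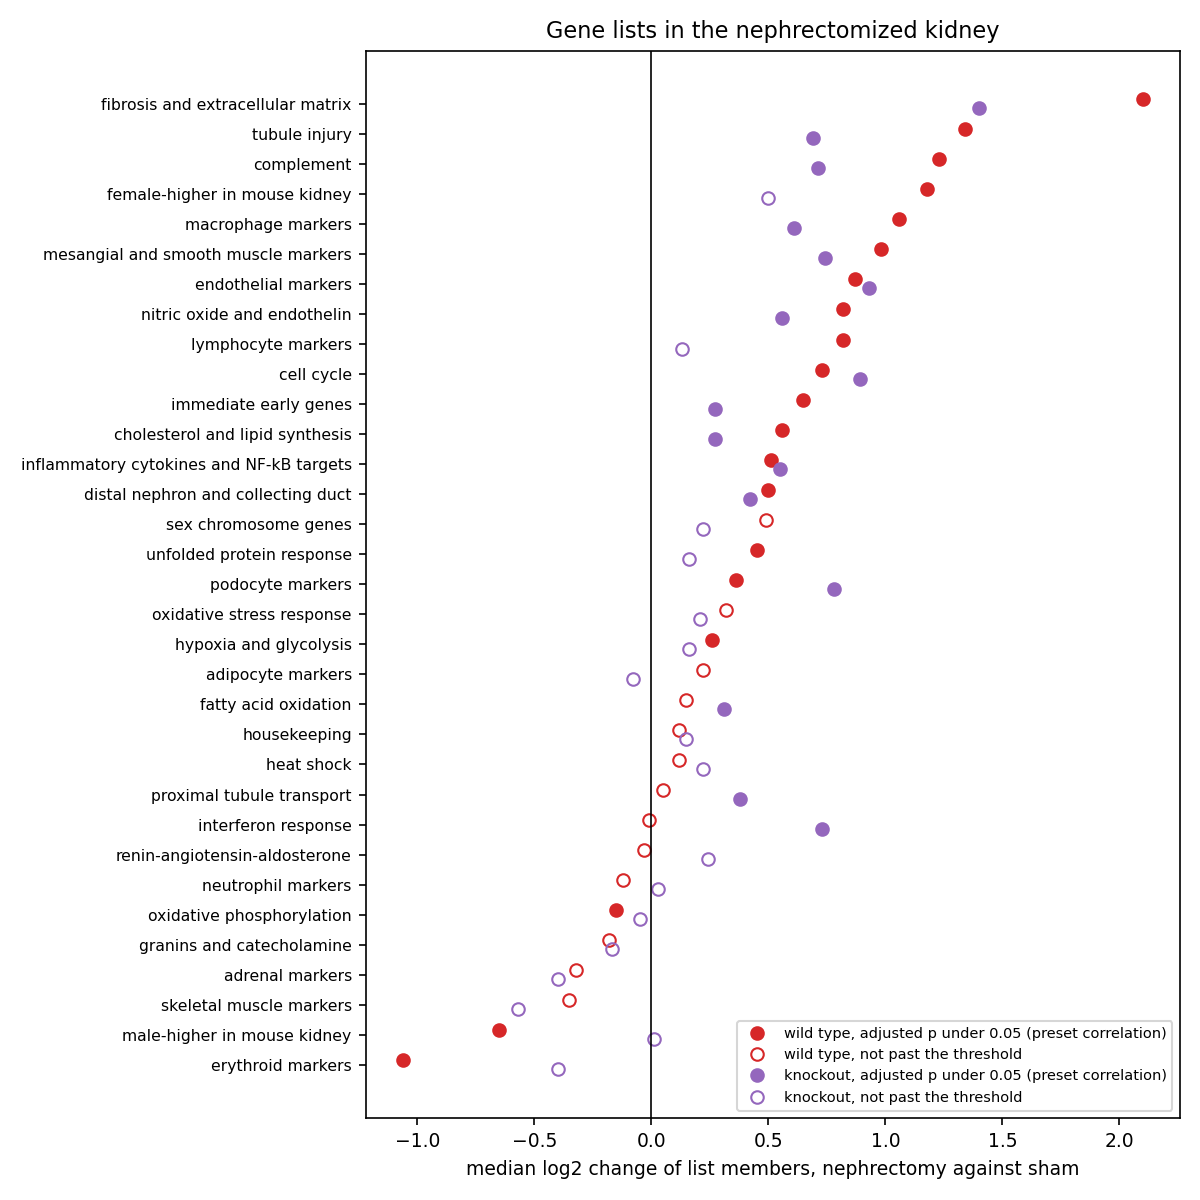
Median log2 change after nephrectomy of the members of each of 33 gene lists, in wild-type (red) and knockout (purple) kidney, where filled points have a camera adjusted p under 0.05 with the preset correlation. The matrix list is highest among the called lists in both genotypes, at 2.1 and 1.4.

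Averaged over both genotypes, a comparison added after the data were seen, nephrectomy raised 139 genes and lowered 17. The slide is mixed with this mean effect, because wild-type sham lay on another slide than both nephrectomy groups. Timp1, an inhibitor of matrix proteases, rose by 3.62 ± 0.61 log2 units (change ± standard error). Its level went from 5.18 ± 2.15 to 10.2 ± 0.77 in wild type and from 7.28 ± 0.9 to 9.5 ± 0.94 in knockout (mean ± SD, n = 4 each). It was above the random-probe level on 1 of 4 wild-type sham and 3 of 4 knockout sham arrays, and its change was 2.53 with the values below that level raised to it. Lum rose by 3.68 ± 0.32, Col3a1 by 3.53 ± 0.43 and the collagen Col1a1 by 2.99 ± 0.47. Krt19 rose by 2.63 ± 0.44, Lcn2 (lipocalin 2, an iron-siderophore binding protein of injured tubules) by 2.45 ± 0.48, Clu (clusterin) by 1.91 ± 0.32 and the adhesion molecule Vcam1 by 1.87 ± 0.27. Macrophage transcripts rose as well, Mpeg1 by 2.71 ± 0.56, the chemokine receptor Cx3cr1 by 2.42 ± 0.49 and the lysozymes Lyz2 and Lyz1 by 1.69 ± 0.29 and 1.52 ± 0.28. Ren1 fell by 2.66 ± 0.25 and Ren2 by 2.55 ± 0.22.

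The matrix list had 15 of 26 members up (25 adjusted over the list alone, median 1.87) and tubule injury 4 of 21 (13 adjusted over the list alone, median 0.95). Mesangial and smooth muscle markers had 2 of 17 up (10 adjusted over the list alone, median 0.84), the actin Acta2 at 1.52 ± 0.26 and the actin-binding Tagln at 1.23 ± 0.24. Cell cycle genes had 0 of 25 past (8 adjusted over the list alone, median 0.61), Mcm6 at 2.2 ± 0.57 and Prc1 at 1.68 ± 0.56. These 4 lists were called with the preset correlation (adjusted p from 2.11e-28 to 1.2e-06) and with an estimated correlation (0.0272 each). Macrophage markers had 5 of 20 up (10 adjusted over the list alone, median 0.84, adjusted p = 0.0583 with an estimated correlation). Complement genes had 2 of 14 up, C3 at 2.73 ± 0.37 and the anaphylatoxin receptor C3ar1 at 1.89 ± 0.3 (9 adjusted over the list alone, median 1.01, adjusted p = 0.0583 with an estimated correlation). Among lymphocyte markers the interleukin 7 receptor Il7r rose by 2.77 ± 0.5 (3 of 19 adjusted over the list alone, median 0.4, adjusted p = 0.166 with an estimated correlation). NF-kB targets had a median of 0.47 with Vcam1 past (2 of 26 adjusted over the list alone, adjusted p = 0.0896 with an estimated correlation). Endothelial markers had a median of 0.88 with 0 of 19 past (6 adjusted over the list alone, Cdh5 at 1.52 ± 0.52, Flt1 at 1.39 ± 0.34, adjusted p = 0.0852 with an estimated correlation). With the random-probe level as a covariate the endothelial median was 0.25 and Cdh5 turned to -0.28. In the hypoxia list Car9, a carbonic anhydrase, fell by 1.78 ± 0.33 while the median was 0.19 (3 rose and 1 fell of 19 adjusted over the list alone, adjusted p = 0.369 with an estimated correlation), and the median turned to -0.12 with that covariate. With the values below the random-probe level raised to it, Il7r was at 2.04, Cx3cr1 at 2, Mpeg1 at 2.47, Krt19 at 2.39, Mcm6 at 1.74 and Prc1 at 1.41.

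Among pancreatic genes, Amy2a5 rose by 6.42 ± 0.43, Try4 by 6.5 ± 0.65, Pnlip by 6.21 ± 0.69, Clps by 5.73 ± 0.62 and Cel (bile salt-stimulated lipase) by 5.56 ± 0.74. Prss2 rose by 5.41 ± 0.5, the trypsin-like 2210010C04Rik by 5.24 and the chymotrypsin Ctrl by 4.88 ± 0.59. The other large falls were in Frem3 (an extracellular matrix protein, at -2.22 ± 0.45), Anxa13 (an annexin of epithelia, -1.86 ± 0.35), Lrrc66 (-1.47 ± 0.29) and Ppp1r1b (an inhibitor of protein phosphatase 1, -1.32 ± 0.2). With the values below the random-probe level raised to it, Amy2a5 was at 6.24, Try4 at 6.13, Pnlip at 5.82, Clps at 4.96, Cel at 4.54, Prss2 at 5.32, 2210010C04Rik at 4.72, Ctrl at 4.57 and Frem3 at -1.38. In limma 165 features were higher and 18 lower (adjusted p from 9e-06 for Amy2a5 to 0.0499 for Mpeg1), and 7790 had an unadjusted p under 0.05. The count was 60 and 90 without wild-type nephrectomy arrays 1 and 4, 103, 65 and 89 without knockout nephrectomy arrays 1, 2 and 3, and 115 and 484 without knockout sham arrays 2 and 4. It was 9 with the random-probe level as a covariate, 92 with the replicate block, 627 with trend and robust eBayes and 669 with only features above the median level.

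Knockout against wild type in sham kidney asks what the loss of chromogranin A does to the kidney of sham-operated mice. Klk1b22, a tissue kallikrein (BC106155, chromosome 7, 51368048 to 51372292), was 20-fold higher in the knockout (12.02 ± 0.29 against 7.7 ± 0.39, n = 4 each). Itpr1, an intracellular calcium channel gated by inositol trisphosphate (AK042240, chromosome 6, 108163089 to 108299717), was 6.33-fold higher (10.92 ± 0.3 against 8.26 ± 0.76). Both had an adjusted p of 0.0335 in limma. Chga itself (BC026554, chromosome 12, 103793206 to 103803236) was at the random-probe level in both genotypes, at 7 ± 0.38 in wild type and 6.68 ± 2.14 in knockout with 2 of 4 arrays above it in each. Its change was -0.32 ± 1.01, and its feature could not check the genotype labels.

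These 2 features were the only ones past the threshold, while 3256 had an unadjusted p under 0.05 and 2.95% did not overlap against 2.86% by chance. The spread was pooled with the nephrectomy groups, whose arrays correlated at 0.858 to 0.892. Sham arrays correlated at 0.71 to 0.869 in wild type and 0.795 to 0.835 in knockout, so p-values between sham groups may be too small. The next smallest p-values, none past the threshold, belonged to Immp2l (1.97 ± 0.32), Speg (-3.2 ± 0.5), 4921536K21Rik (-1.94 ± 0.31) and Sh3rf3 (-2.63 ± 0.43) at an adjusted p of 0.166, and to Zbtb25 (2.14 ± 0.38) and Paip1 (-2.56 ± 0.45) at 0.225. Raised to the random-probe level where they were below it, Speg was at -0.83, 4921536K21Rik at -1.54, Sh3rf3 at -0.9 and Zbtb25 at 1.71. Havcr1 (kidney injury molecule 1) was at 2.14 ± 0.52, with an adjusted p of 0.365. None of 33 lists was called by camera. Lymphocyte markers (median 0.71) and endothelial markers (-0.34) had the smallest adjusted p, 0.102, and adjusted p = 0.881 with an estimated correlation. The groups lay on different slides, and single arrays decided the counts. Leaving out wild-type sham array 1, 2 or 3 or knockout sham array 3 ended both calls, leaving out wild-type sham array 4 or knockout sham array 1 or 2 left 1 feature, and leaving out knockout sham array 4 gave 11. The count was 0 with quantile normalization or the replicate block and 9 with trend and robust eBayes. It was 3 with only features above the median level, and 1 with array weights, gene averages, only the 2 compared groups, the table with matched columns, the random-probe covariate or without wild-type sham arrays 3 and 4. The list count was 7 without wild-type sham array 4, 4 without knockout sham array 4 and 1 without knockout sham array 1 or 3.

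After nephrectomy, knockout against wild type asks whether the failing kidney differs without chromogranin A. In the matrix list 0 of 26 members passed the test, and the list as a whole had a median of -0.69 in the knockout, with 25 members negative and a camera adjusted p of 2.13e-08 (adjusted p = 0.582 with an estimated correlation). Over the alternatives this median ranged from -0.89 to -0.41. The list score of an array is the mean log2 level of its members relative to all kidney arrays. The matrix score ranged from 0.74 to 1.92 over the wild-type arrays and from 0.06 to 0.99 over the knockout arrays. The acinar list, written after the data were seen, moved the other way in this comparison, with 25 of 27 members positive, a median of 0.88 and an adjusted p of 0.00436 (adjusted p = 0.737 with an estimated correlation). Lox, which cross-links collagen, was at -1.54 ± 0.7 and Col6a1 at -1.33 ± 0.58. Tubule injury genes had a median of -0.52 (17 of 21 negative, adjusted p = 0.582 with an estimated correlation), with Havcr1 at 1.71 ± 0.52 and Lcn2 at -1.66 ± 0.67. Over the alternatives this median ranged from -0.7 to -0.26. The tubule injury score ranged from 0.06 to 1.42 over the wild-type arrays and from 0.15 to 0.53 over the knockout arrays. Lcn2 was at 14.02, 11.39, 11.42 and 13.83 on the wild-type arrays and at 10.64 to 11.25 on the knockout arrays. Genes higher in male kidney had a median of 0.89 (9 of 9 positive, adjusted p = 2.91e-06, adjusted p = 0.582 with an estimated correlation), with Cyp7b1 at 1.8 ± 0.63 and Slc7a13 at 1.5 ± 0.64. Over the alternatives this median ranged from 0.44 to 1.16. The score of these genes ranged from -2.07 to 0.28 over the wild-type arrays and from 0.23 to 0.35 over the knockout arrays. That of genes higher in female kidney, a list not called here, ranged from 0.24 to 1.21 and from -0.24 to 0.73. The sex of the mice was not part of the fit. Interferon genes had a median of 0.44 (21 of 21 positive, adjusted p = 0.599 with an estimated correlation), with Mx2 at 1.43 ± 0.72 and Ifit1 at 1 ± 0.72.

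Proximal tubule transport had a median of 0.26 (20 of 23 positive, adjusted p = 0.655 with an estimated correlation), with the organic anion transporter Slc22a7 at 2.63 ± 0.75. Oxidative phosphorylation had one of 0.24 (21 of 23 positive, adjusted p = 0.599 with an estimated correlation), with Cox7a2 at 0.6 ± 0.46 and Sdhc at 0.48 ± 0.3. Mesangial and smooth muscle markers had a median of -0.54 (adjusted p = 0.582 with an estimated correlation), with Pdgfrb at -0.94 ± 0.45 and Lmod1 at -0.91 ± 0.57. Immediate early genes (-0.22, adjusted p = 0.599 with an estimated correlation) and complement (-0.24, adjusted p = 0.656 with an estimated correlation) were also called downward. In none of these 9 lists did a member pass the threshold, over all features or adjusted over the list alone.

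In limma 0 features passed after nephrectomy between genotypes, and 1 with trend and robust eBayes or with only features above the median level. The smallest adjusted p was 0.215, 1997 features had an unadjusted p under 0.05, fewer than the 2208 that chance gives, and 5.80% did not overlap against 2.86% by chance. The fit pooled the spread of all 4 kidney groups. Arrays correlated at 0.873 to 0.892 in wild-type and 0.858 to 0.887 in knockout nephrectomy, against 0.71 to 0.869 and 0.795 to 0.835 in sham. The pooled spread may make p-values after nephrectomy too large, so the count of 1997 does not show a genotype effect below chance. The smallest p belonged to Thnsl2, a threonine synthase-like enzyme (BC025604, chromosome 6, 71078391 to 71094314), at 13.27 ± 0.3 against 10.91 ± 0.63 (n = 4 each, change 2.36 ± 0.34). Among features with a gene symbol it was followed by Tacr2 (2.94 ± 0.49) and the nonagouti gene (3.21 ± 0.55) at an adjusted p of 0.403 and Etnppl (3.04 ± 0.57) at 0.557. Gm13713 (-2.68 ± 0.54), Gm5782 (-3.04 ± 0.62) and Cyp2c53-ps (-2.96 ± 0.61) had an adjusted p of 0.627 and Tut1 (-2.74 ± 0.57) one of 0.653. With the values below the random-probe level raised to it, Tacr2 was at 0.82, the nonagouti gene (above that level on 1 of 8 arrays) at 0.38, Gm13713 at -1.24, Gm5782 at -0.96, Cyp2c53-ps at -0.62 and Tut1 at -0.72. Chga was at 7.11 ± 0.72 in wild type and 6.65 ± 2.1 in knockout. Both groups lay on slide 2. The list count was 5 without wild-type nephrectomy array 1, and 2 features and 1 feature passed without wild-type nephrectomy array 4 and knockout nephrectomy array 3.

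Whether nephrectomy acted differently in the 2 genotypes was tested as the difference of the effects. The matrix list differed by a median of -0.5 over 26 genes, lower in the knockout (23 negative, camera adjusted p = 0.00362, adjusted p = 0.858 with an estimated correlation), with Timp1 at -2.8 ± 1.22 and Lox at -1.89 ± 0.98. In wild-type sham Timp1 was above the random-probe level on 1 of 4 arrays and Lox on 2, and with the values below it raised to it they were at -1.12 and -1.68. The acinar list, written after the data were seen, moved the other way, with a median of 0.35, 20 of 27 members positive and an adjusted p of 0.0445 (adjusted p = 0.59 with an estimated correlation). Genes higher in male kidney differed by 0.78 (9 of 9 positive, adjusted p = 0.00362, adjusted p = 0.858 with an estimated correlation), with Cyp7b1 at 1.39 ± 0.89 and Slc7a13 at 1.58 ± 0.9. The wild-type nephrectomy arrays, whose score for these genes ranged from -2.07 to 0.28, enter this difference. Interferon genes differed by 0.66 (Mx2 at 2.37 ± 1.02, Ifi44 at 1.41 ± 0.8, adjusted p = 0.00719), proximal tubule transport by 0.34 (0.00719) and lymphocyte markers by -0.56 (0.0212). For each of these 3 lists too the adjusted p was 0.858 with an estimated correlation. In all 5 lists 0 members passed, over all features or adjusted over the list alone.

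In limma 0 features passed for the difference (smallest adjusted p 1), as with trend and robust eBayes, and 1911 had an unadjusted p under 0.05, fewer than the 2208 that chance gives. The smallest p belonged to Pax9 (4.46 ± 0.82), EG668249 (4.14 ± 0.79), Cyp2c70 (2.28 ± 0.5) and Elapor2 (3.62 ± 0.82) upward. Downward it belonged to Gnpda2 (-2.1 ± 0.39), Jmjd1c (-2.71 ± 0.55), Itpr1 (-2.25 ± 0.49) and Gm3811 (-3.31 ± 0.73). Raised to the random-probe level where they were below it, Pax9 was at 1.88, EG668249 at 1.16, Cyp2c70 at 1.69, Elapor2 at 2.97, Gnpda2 at -1.53, Jmjd1c at -2.56 and Gm3811 at -1.63. The slide enters this difference through wild-type sham. The list count was 2 and 8 without wild-type nephrectomy arrays 1 and 2, and 3 without wild-type sham array 1 or 2, knockout sham array 1 or knockout nephrectomy array 1.

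Averaged over both surgeries, a comparison also added after the data were seen, 0 features passed between genotypes in limma, and 28 with trend and robust eBayes (3283 at an unadjusted p under 0.05). Among the features that shared the smallest adjusted p, 0.0779, were Klk1b22 (2.83 ± 0.4), Thnsl2 (1.58 ± 0.24), Itpr1 (1.54 ± 0.24), Ndufaf1 (an assembly factor of complex I, 1.18 ± 0.19), Paip1 (-2.07 ± 0.32), BC018473 (-3.33 ± 0.51) and the neuropeptide Npy (1.98 ± 0.32). Ephb3 (-1.94), 4921536K21Rik (-1.17) and Havcr1 (1.92 ± 0.37) had one of 0.169. Camera called 5 lists lower in the knockout, namely matrix (-0.5, Col6a1 at -0.95 ± 0.41), tubule injury (-0.4), mesangial (-0.3), endothelial (-0.32) and nitric oxide and endothelin genes (-0.3). It called genes higher in male kidney (0.48) and oxidative phosphorylation (0.15) upward. Each of the 7 had an adjusted p = 0.72 with an estimated correlation and 0 members past, and adjusted over the list alone 1 tubule injury gene was higher. The acinar list had a median of 0.41 (24 of 27 positive, adjusted p = 0.205). The slide is mixed with the genotype here too. The list count was 12 without wild-type sham array 4 or wild-type nephrectomy array 2, 2 without wild-type nephrectomy array 1, 3 without knockout sham array 2 and 4 without knockout sham array 3, wild-type nephrectomy array 4 or knockout nephrectomy array 4. The feature count was 18 with only features above the median level, 8 with array weights and 7 with gene averages. Without knockout sham array 4, 6 features passed, and 1 passed without wild-type sham array 4 or knockout nephrectomy array 1.

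In CRL-1927 cells, CHGA treatment was compared with control to ask what adding the recombinant protein does to mesangial cells. No sample controls for other contents of the added preparation, so their effect cannot be told apart from that of CHGA. Lcn2, an iron-siderophore binding protein (BC132069, chromosome 2, 32240184 to 32243259) rose 23.4-fold, from 9.82 ± 0.25 to 14.37 ± 0.06 (mean ± SD, n = 4 each). Saa3, an acute phase protein (BC055885, chromosome 7, 53967367 to 53971046), rose at least 44.4-fold, from 4.89 ± 1.36 to 12.06 ± 0.21. The neutrophil chemokines Cxcl5 and Cxcl1 rose 23.5-fold (7.12 ± 0.55 to 11.67 ± 0.16) and 18.9-fold (8.44 ± 0.53 to 12.68 ± 0.19). Complement component C3 rose 12.8-fold (10.52 ± 0.42 to 14.2 ± 0.19) and the monocyte chemokine Ccl2 4.28-fold (10.88 ± 0.23 to 12.97 ± 0.28).

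Steap4, a metalloreductase, rose 42.3-fold, the secreted protease inhibitor Slpi 9.20-fold and the complement protease C1s1 7.59-fold, on the feature with the smallest p among its 3 past the threshold. The fall was in Gm2220, a predicted gene, at least 1.71-fold lower. Fgf7, a fibroblast growth factor for epithelia, rose 3.50-fold and the lipid phosphatase Plpp3 3.41-fold, both named after their values were seen. Of 26 inflammatory cytokines and NF-kB targets 4 rose, 0 fell and 22 did not pass, while 16 rose adjusted over the list alone. The median was 0.79 and the camera adjusted p 9.28e-19. Of 21 interferon genes 0 passed and 3 rose adjusted over the list alone, with a median of 0.21, Ifi44 at 1.07 ± 0.29 and Cxcl10 at 0.76 ± 0.16. These 2 lists also passed with an estimated correlation, at 0.00473 and 0.0367, and the other 5 called lists did not.

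Complement genes had 2 of 14 up (4 adjusted over the list alone, median 0.6), with an adjusted p of 0.000436, and adjusted p = 0.0597 with an estimated correlation. Over the alternatives this median ranged from 0.06 to 1.42. Neutrophil markers had Lcn2 up of 14 (1 adjusted over the list alone, median 0.15, adjusted p = 0.472 with an estimated correlation). Lcn2 was also the 1 member of 21 tubule injury genes that passed (3 adjusted over the list alone), a list that was not called. Downward, matrix genes had a median of -0.33 with 0 of 26 past (2 fell adjusted over the list alone, Postn at -1.75 ± 0.48, Col3a1 at -1.38 ± 0.98, adjusted p = 0.0742 with an estimated correlation). Cholesterol synthesis genes had one of -0.22 with 0 of 20 past and 18 negative (Lss at -0.69 ± 0.26, Nsdhl at -0.43 ± 0.21, adjusted p = 0.221 with an estimated correlation). Renin-angiotensin-aldosterone genes had one of -0.38 with 0 of 15 past (Ren1 at -1.79 ± 1.28, Ace at -1.71 ± 0.6, adjusted p = 0.115 with an estimated correlation). Raising the values below the random-probe level to it made Steap4 36-fold higher and put Postn at -0.78, Col3a1 at -0.05, Ren1 at -0.61 and Ace at -0.87. Chga was at the random-probe level, at 6.92 ± 0.71 in control and 7.04 ± 0.37 in treated cells.

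In limma 13 features (11 genes) were higher and 1 lower, at adjusted p from 0.000404 (Lcn2) to 0.0341 (Ccl2). An unadjusted p under 0.05 was reached by 2501 features, and 4.01% did not overlap against 2.86% by chance. The count fell to 7 and 5 without control samples 3 and 4 and to 7, 5, 8 and 6 without treated samples 1, 2, 3 and 4. With the replicate number as a replicate block it was 0, with trend and robust eBayes 110 and with only features above the median level 36. All 8 cell arrays lay on 1 slide.

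**Figure D4:**
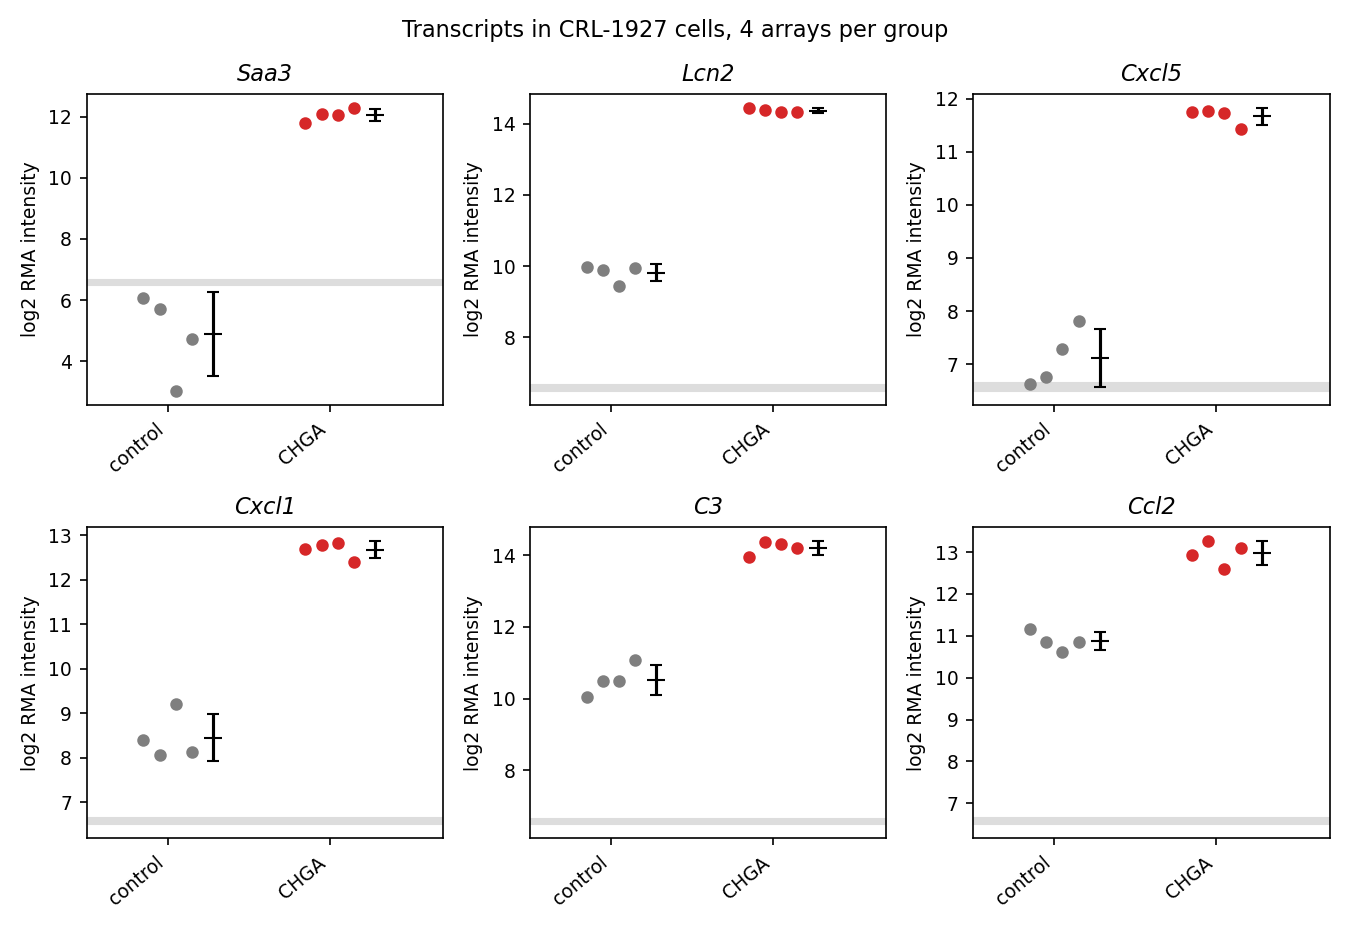
Log2 RMA intensity of Saa3, Lcn2, Cxcl5, Cxcl1, C3 and Ccl2 in control and CHGA-treated CRL-1927 cells, where points are arrays, the black mark is the mean ± SD of 4 arrays and the grey band is the range of the random-probe level over the arrays. Each treated array lies above all 4 control arrays for these 6 genes.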

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

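The tests of pancreatic admixture, slide, array background, matrix against acinar score and exchanged columns were chosen only after the results were seen.

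Over both genotypes 20 of 27 acinar genes rose after nephrectomy (24 adjusted over the list alone, median 4.05), Amy2a5 to 13.93 ± 0.85 in wild type and 14.41 ± 0.4 in knockout, while Klk1, a member that kidney also expresses, was at 14.2 ± 0.2 in wild-type sham and 14.26 ± 0.2 after nephrectomy. The tables argue against the slide, since the lowest acinar score of a nephrectomized array lay 1.58 log2 units above the highest of a knockout sham array on the same slide, and against array background, since the median change was 3.97 with the random-probe level as a covariate (4 acinar genes then still past the threshold). Over the 8 nephrectomized arrays an acinar gene correlated with the mean of the others at a median r of 0.96 (0.97 within genotype, lowest -0.3, highest 1), as a single admixed source of acinar RNA needs, so pancreatic tissue taken with the remnant kidney is a candidate explanation, and acinar genes switched on in the kidney itself stay open, as untested. Islet genes, which such tissue holds as well, go against it in that 0 of 7 passed the threshold (median -0.77, Ins1 at -0.77 ± 0.52, Ins2 at -0.22 ± 0.49), but 0 of 7 lay above the median level of all features, and how much islet RNA a piece of pancreas would bring was not measured. Whether such tissue also brought matrix transcripts was not decided: the matrix and acinar scores had an r of -0.199 (exact permutation p = 0.639) and a Spearman rho of -0.095 (exact permutation p = 0.84) over 8 arrays, the only such relation computed, and r was 0.354 without the 2 arrays farthest from the median acinar score.

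Nephrectomized arrays also had a lower random-probe level than sham arrays, by 0.47 log2 units over all kidney arrays (exact permutation p = 0.000777) and by 0.46 within slide 2 (exact permutation p = 0.00404), against 0.01 between the cell groups (exact permutation p = 0.886). With that level as a covariate, 10 of the 20 lists called upward over both genotypes lost the larger part of their median, so for these lists array background and surgery cannot be told apart, because the background differs between the surgery groups themselves. For the matrix list the tables argue against background as the whole cause: its median moved from 1.87 to 1.16 and stayed past the threshold with the preset correlation (adjusted p = 9.73e-14), though not with an estimated correlation (adjusted p = 0.169). A change of the kidney's own RNA after nephrectomy, the biological explanation the design names, stays open as untested.

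In the deposited value table, 8 of the 8 columns of knockout sham and wild-type nephrectomy matched the same-numbered array of the other group (r 0.831 to 0.871, against -0.137 to 0.049 with their own array), so table and files carry these group labels exchanged. Whether the files hold the wrong ones was tested on 355 features within 10 Mb of Chga, where a targeted locus may carry sequence of the donor strain. With the files' labels 3.38% of them differed between genotypes at p under 0.01 against 1.79% elsewhere (odds ratio 1.92, interval 0.978 to 3.42, Fisher exact p = 0.0404). With the labels exchanged 6.48% did against 5.28% (odds ratio 1.24, interval 0.776 to 1.9, Fisher exact p = 0.285), and as the 95% intervals overlap this test decides neither way. With the arrays exchanged, 0 features passed for nephrectomy over both genotypes and 183 for the genotype over both surgeries. The exchange makes these 2 comparisons trade places by construction, so the counts cannot show which labels are right. No biological explanation was tested.

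Other splits of the samples were counted for each number of features past the threshold. For nephrectomy in wild type 1 of 35 splits, the real one with 19, gave as many (highest other 1). The same holds for nephrectomy in knockout (1 of 35, 12 against 0), for nephrectomy over both genotypes (1 of 100, 183 against 1) and for CHGA in cells (1 of 35, 14 against 0). A share of 1 in 35 is the smallest that 35 splits can give, before any allowance for the number of comparisons. A wrong split also moves a real effect into the spread within groups, which lowers its count. These counts therefore cannot exclude chance. Nor can it be excluded for the genotype in sham kidney, where 6 of 35 splits gave at least as many as the 2 features Klk1b22 and Itpr1 and the highest other gave 1849. That split sets wild-type sham arrays 1 and 2 and knockout sham arrays 3 and 4, the sham arrays with the lowest random-probe intensity, against the other 4, and so points to a structure of the samples. A split with knockout sham array 4 and wild-type sham arrays 1, 2 and 3 on 1 side gave 661. Where 0 features passed, each split gives at least as many by construction, so the count says nothing about chance. This holds for the genotype after nephrectomy (35 of 35 splits, highest other 2), the difference of the effects (100 of 100, highest other 10) and the genotype over both surgeries (100 of 100, highest other 1).

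In 7 of 98 groups of 4 arrays tested a single array stood far from the other 3, where chance gives about 4.9. Try4 was at 4.49 in wild-type sham array 2 and at 7.88 to 8.1 in the others. Itpr1 was at 9.4 in wild-type sham array 4 (others 7.83 to 7.91). In wild-type nephrectomy array 1, Col1a1 was at 13.63 (others 11.65 to 11.81) and Thnsl2 at 9.97 (others 11.1 to 11.32). Chga was at 3.51 in knockout nephrectomy array 4 (others 7.42 to 7.87). In cells, Lcn2 was at 9.45 in control sample 3 (others 9.9 to 9.98) and Cxcl5 at 11.43 in treated sample 4 (others 11.73 to 11.77).

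The nephrectomy effect differed between the genotypes, by the preset camera test of the difference, for 5 lists: the matrix list by -0.5 in the median, lymphocyte markers by -0.56, interferon genes by 0.66, proximal tubule transport by 0.34 and genes higher in male kidney by 0.78. With an estimated correlation each had an adjusted p of 0.858.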

How the results depend on the processing

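The table with matched columns, the exchanged arrays, the random-probe covariate, the runs without wild-type sham arrays 3 and 4 or without acinar features, and all alternatives of the 2 mean effects were chosen only after the data were seen. The gene calls followed here are those of the named genes, mostly picked for large changes, so their shares do not describe all features past the threshold. Of 77 such calls, 77 kept their side of the threshold with a fold of at least 1.5, 75 with trend and robust eBayes and 73 with array weights. It was 71 in the table with matched columns, 66 with median centring and 64 each with quantile normalization and gene averages. It was 38 with the replicate block, 30 of 64 without wild-type sham arrays 3 and 4, 10 of 64 with the random-probe covariate and 4 of 32 with the 2 compared groups alone. With only the kidney arrays of slide 2 it was 6 of 12, without acinar features 31 of 44 and with 1 array left out 570 of 872. No direction turned in these. Feature counts are given in the order nephrectomy in wild type (19), nephrectomy in knockout (12), genotype in sham (2), genotype after nephrectomy (0), nephrectomy over both genotypes (183), genotype over both surgeries (0) and cells (14), where they moved beyond 1.5 times. With the value table as labelled they were 1, 1, 106, 41, 5 and 455. With matched columns they were 106, 41, 1, 1, 455 and 5, and with the arrays exchanged 2, 0, 19, 12, 0 and 183. Exchanging the 2 groups turns each nephrectomy comparison into a genotype comparison. The counts of the exchanged arrays are therefore those of the main run in another order, by construction. In the same way the counts of the table as labelled are those of the table with matched columns. With only features above the median level they were 143, 39, 669 and 18 for nephrectomy in wild type, in knockout, over both genotypes and the genotype over both surgeries, 1 for the genotype after nephrectomy and 36 in cells, where fewer features are tested. With trend and robust eBayes they were 179, 51, 9, 1, 627, 28 and 110. Array weights gave 29 for nephrectomy in knockout, 1 for the genotype in sham and 8 over both surgeries, and gene averages 1 and 7 for these genotype comparisons. The replicate block gave 5 for nephrectomy in knockout, 0 for the genotype in sham, 92 for nephrectomy over both genotypes and 0 in cells. With only the 2 compared groups the counts were 0, 3 and 1 for nephrectomy in wild type, in knockout and the genotype in sham (fewer arrays), and quantile normalization gave 0 for the last. With the random-probe covariate they were 1 and 2 for nephrectomy in wild type and knockout, 1 for the genotype in sham and 9 for nephrectomy over both genotypes. Without wild-type sham arrays 3 and 4 they were 3 for nephrectomy in wild type, 1 for the genotype in sham, 69 for nephrectomy over both genotypes and 1 for the genotype over both surgeries. Without acinar features they were 8 and 0 for nephrectomy in wild type and knockout. For the difference of effects it was 0 in each run, a comparison that the exchange of the 2 groups leaves unchanged. The cause of these moves was not tested, also where fewer arrays or features are named. Leaving out each array in turn gave 6 to 23, 3 to 23, 0 to 11, 0 to 2, 60 to 484, 0 to 6 and 5 to 13. The number of called lists ranged from 0 to 7 for the genotype in sham, 5 to 13 after nephrectomy, 2 to 8 for the difference and 2 to 12 over both surgeries in the same runs. With an estimated correlation the called lists numbered 2 and 0 for nephrectomy in wild type and knockout, 4 over both genotypes, 0 for the genotype after nephrectomy, the difference and the genotype over both surgeries, and 2 in cells. Of 87 list calls 8 held. With the random-probe covariate they numbered 13, 8 and 13 for nephrectomy in wild type, knockout and both, and 1 for the genotype in sham. With features above the median level they numbered 8 for the difference, and with gene averages 3 in cells. List medians that turned with the covariate (14 of 80 calls) were, in wild type, distal nephron -0.51, podocyte -0.42, endothelial -0.04 and hypoxia -0.14. In knockout they were proximal tubule 0, distal nephron -0.13, fatty acid oxidation -0.09 and cholesterol synthesis -0.01. Over both genotypes they were distal nephron -0.29, podocyte -0.09, fatty acid oxidation -0.34, hypoxia -0.12, oxidative stress -0.05 and cholesterol synthesis, whose test turned at a median of 0.02. Cdh5 over both genotypes was at -0.28. In the value table as labelled, whose construction exchanges 2 groups, the following turned. After nephrectomy in wild type, Amy2b was at -0.16, Prss2 at -0.34, the nonagouti gene at 0.14, Col1a2 at -0.16, Mpeg1 at -0.81, Egr2 at -0.03 and Cyp7b1 at 0.31. After nephrectomy in knockout, Ren2 was at 0.4, Ren1 at 0.05, Cd44 at -0.51, Cx3cr1 at -0.27, C3 at -0.96, Flt1 at -0.43 and Cdh5 at -0.37. Between genotypes in sham, Immp2l was at -0.18 and Sh3rf3 at 0.32. After nephrectomy Tacr2 was at 0, the nonagouti gene at -0.67, Etnppl at -0.39, Lox at 1.41, Col6a1 at 1.43 and Lcn2 at 1.63. In that comparison Slc22a7 was at -0.33, Pdgfrb at 0.24, Lmod1 at 1.07, Cox7a2 at -0.43 and Sdhc at -0.2. For nephrectomy over both genotypes, Anxa13 was at 1.09, Lrrc66 at 0.28, Ppp1r1b at 0.39, Col3a1 at -0.19, Col1a1 at -0.63, Krt19 at -0.12, Lcn2 at -0.92, Clu at -0.67, and Vcam1 at -0.19. Mpeg1 was at -0.36, Cx3cr1 at -0.59, Lyz2 at -0.36, Lyz1 at -0.4, and Il7r at -0.08. C3 was at -0.34, C3ar1 at -0.06, Acta2 at -0.23, Tagln at -0.28, Cdh5 at -0.15 and Flt1 at -0.78. For the genotype over both surgeries, Klk1b22 was at -1.3, Thnsl2 at -0.56, Ndufaf1 at -0.52, 4921536K21Rik at 0.09, Col6a1 at 1.83 and Npy at -0.79. Chga between genotypes was at 0.1 in sham and 0.02 after nephrectomy with matched columns. With 1 array left out it ranged from -1.01 to 0.56 in sham, -0.87 to 0.59 after nephrectomy and -0.07 to 0.44 in cells. Signal over background limits dim features: the median SD within kidney groups was 1.33 for the dimmest features and 0.43 for the brightest.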

Other observations

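The pancreatic islet, liver and circadian clock lists and the test on clock genes were chosen only after the data were seen. Hormone genes of the pancreas did not pass with the acinar genes. Over both genotypes 0 of 7 islet genes passed after nephrectomy and their median change was -0.77 (camera adjusted p = 0.0762), with insulin Ins1 at -0.77 ± 0.52 and glucagon Gcg at -0.81 ± 0.47. Of these islet genes 0 lay above the median level of all features, so a small rise could have been missed. Of 14 liver genes 0 passed (median -0.49, adjusted p = 0.266), albumin (Alb) at -0.81 ± 0.53 and transthyretin (Ttr) at 1.64 ± 0.66. Of 16 circadian clock genes 0 passed (median 0.21, adjusted p = 0.251).

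Other gene groups called over both genotypes after nephrectomy had 0 members past the threshold over all features. Podocyte markers had a median of 0.56 (3 of 16 rose adjusted over the list alone, adjusted p = 0.116 with an estimated correlation), distal nephron genes 0.56 (4 of 21, adjusted p = 0.259 with an estimated correlation), and nitric oxide and endothelin genes 0.55 (4 of 23, adjusted p = 0.0879 with an estimated correlation). Medians were 0.64 for immediate early genes (3 of 20, adjusted p = 0.116 with an estimated correlation), 0.42 for cholesterol synthesis genes (3 of 20, adjusted p = 0.166 with an estimated correlation) and 1.07 for genes higher in female kidney (2 of 6, adjusted p = 0.19 with an estimated correlation). Interferon genes were at 0.37 (adjusted p = 0.441 with an estimated correlation), and fatty acid oxidation at 0.24 (adjusted p = 0.441 with an estimated correlation). The other lists called upward were the unfolded protein response at 0.24 (adjusted p = 0.116 with an estimated correlation) and oxidative stress genes at 0.21 (adjusted p = 0.166 with an estimated correlation). Erythroid markers were at -0.99 (3 of 9 fell adjusted over the list alone, adjusted p = 0.192 with an estimated correlation), skeletal muscle markers at -0.3 (adjusted p = 0.116 with an estimated correlation) and genes higher in male kidney at -0.31 (adjusted p = 0.492 with an estimated correlation). With the random-probe level as a covariate the median turned to -0.09 for podocyte markers, -0.29 for distal nephron genes, -0.34 for fatty acid oxidation and -0.05 for oxidative stress genes. It was 0.02 for cholesterol synthesis, 0.09 for nitric oxide and endothelin genes, 0.17 for interferon genes and 0.26 for genes higher in female kidney. Not called were neutrophil markers (median -0.05), proximal tubule transport (0.21), renin-angiotensin-aldosterone genes (0.09, with Ren1 past the threshold as 1 of 15), oxidative phosphorylation (-0.15), granins and catecholamines (-0.27), heat shock (0.03), adrenal (-0.37) and adipocyte markers (0.19), sex chromosome genes (0.29) and housekeeping genes (0.14).

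Across features, which are not independent replicates, the nephrectomy effects in wild type and knockout correlated at 0.343 over 44170 features and at 0.596 over the 22085 above the median level. The genotype effects in sham and after nephrectomy correlated at 0.088 and 0.272. Of the 12 features past the threshold in knockout, 12 had the same sign in wild type, and 7 acinar genes are among them.

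A hypothesis on the clock genes was tested on the data it came from. Dbp, a transcription factor under direct clock control, was at 1.26 ± 0.35 in the knockout against wild type in sham and 1.83 ± 0.35 after nephrectomy (1.55 ± 0.25 over both, adjusted p = 0.0779), and Ciart at 1.29 ± 0.5 and 1.47 ± 0.5. Arntl, a transcription factor whose peak lies in the opposite phase, was at -1.28 ± 0.58 and -2.09 ± 0.58 and Npas2 at -1.33 ± 1.04 and -2.21 ± 1.04. Other members went against this pattern, Per1 at -1.25 ± 0.56 and -0.48 ± 0.56, Per2 at -0.45 ± 0.54 in sham and Clock at 0.27 ± 0.88 in sham. None passed over all features, and 5 of 16 rose and 1 fell over both surgeries adjusted over the list alone. If the genotypes had been collected at different times of day, the effects in sham and after nephrectomy would go together. Dbp and Arntl, in which the pattern was seen, were left out. Across the other 14 clock genes, which are not independent replicates, the effects correlated at 0.75, as high as in 2.52% of 10000 random lists (median 0.3). The random genes were matched by level but not by shared regulation, so this share cannot exclude chance. A difference in collection time is a candidate explanation, to which Per1 runs counter, beside an effect of the knockout on the clock, which was not tested. Collection times are not given in the sources used here.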
